A study of Mus musculus with 2 samples.

How the data were processed

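The study holds 2 single-cell libraries of the female mouse pituitary at postnatal day 4, made with 10x Chromium 3' chemistry from 1 mouse each, per the labels' protocols: Hesx1Cre/+ (control library) and Hesx1Cre/+; R26 dnRAR/dnRAR (dnRAR library). Tissue was dissociated with collagenase and trypsin at 37°C, and 17400 cells were loaded for a target of 10000, per the labels' protocols. The deposited tables hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.0.2 and STAR on mm10, per the file headers and the submitters' processing notes, which also name Seurat 3.0.2. No Seurat output was used here. The values were checked to be whole numbers. Of 31054 feature IDs, 31011 were found in the GENCODE vM21 annotation (mm10), which gave the positions.

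Barcodes with at least 500 detected genes and at most 15% of counts from mt- genes were kept: 581 control and 796 dnRAR barcodes failed the first limit and 197 and 391 the second. A Scrublet-type score, the share of simulated doublets (2 per cell) among each cell's neighbours, was computed in each library, and the top-scoring 366 and 349 cells were removed, the share expected at 7.6% multiplets per 10000 cells, which left 6235 and 5949 cells (85.6% and 81.6% of barcodes) with 46830904 and 41684440 UMIs. Both libraries were clustered together: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked within each library without hormone, mt-, ribosomal protein (symbols that start with Rpl or Rps) and haemoglobin genes, and 30 principal components gave a shared-neighbour graph of 20 neighbours for Leiden clustering at resolution 1, with 26 clusters. No integration step was used. Clusters were named by fixed marker lists. A class needed at least 3 of its markers at 2-fold or more over the median CPM of the other clusters (10 CPM added to both) and 1 marker among the cluster's 10 genes with the highest fold. The summed log2 fold of the markers in those 10 decided between classes, and a cluster with more markers of another class there stayed unnamed. Erythroid markers did not count against a name, because free haemoglobin RNA was found in every cluster. Different clusters held most of the somatotrope-like and stem/progenitor-like cells in each library, so these clusters cannot be separated from the library; values are given per class. Of the leading genes of clusters, the hormone genes were left out of clustering. Single values of Ghrhr, Aldh1a2, Tbx19, Spp1, Pcsk2 and Oacyl within their class are given as CPM and not as results. Some leading genes also count in the lists of their class. Examples are Hes1 (clusters 4 and 19, Notch), Cldn4 (cluster 2, epithelial-mesenchymal transition) and Resp18 (clusters 3 and 20, secretory granule). Those list values are not independent of the clustering. Values over all cells use no clusters.

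UMI counts were summed per library over all kept cells and per class with at least 100 cells in both libraries (11 classes), and for hormone and marker genes in the melanotrope-like class. CPM scales the summed count of a gene by the summed counts of all genes, with an exact Poisson interval; ratios of CPM and of shares have an exact conditional binomial interval and shares an exact Clopper-Pearson interval, all at 95% and for counting error only. UMIs of 1 cell and cells of 1 mouse are not independent samples of a genotype, so no test of genotype and no p-value was made. Counts of genes that differ describe these 2 libraries only. Log2 ratios use CPM + 5. A gene counted as measured at 5 CPM or more in either library. For 17 gene lists fixed before the data were examined, the median log2 ratio was given with an interval from 1000 Poisson draws of the counts and its percentile among 10000 random lists of the same size, each member drawn from the 50 measured genes nearest in mean CPM; a list needed 3 measured members. The lists were hormones, retinoic acid targets, retinoic acid synthesis and receptors, pituitary transcription factors, secretory granule, hypothalamic and feedback receptors, cell cycle, Notch, Wnt, BMP and FGF, epithelial-mesenchymal transition, thyroid hormone responsive, unfolded protein response, dissociation and heat stress, p53 and apoptosis, interferon response and mitochondrial transcripts. The rule for named genes, also fixed before the data were examined, took every measured hormone and retinoic acid gene; the 10 highest and 10 lowest log2 ratios over all cells and up to 6 each per class, among genes with at least 20 CPM in one library, 50 UMIs in all and an interval without 1, leaving out hormone, mt-, ribosomal protein and haemoglobin genes; and the 4 members of each list furthest from 0 in stem/progenitor-like and somatotrope-like cells. The text gives a part of these members, chosen after their values were seen, and the result tables give all. Outside this rule, the melanotrope markers in melanotrope-like cells, Foxp2 and Gnrhr in thyrotrope-like cells, Prop1, Tbx19 and Rab6a were added after their values were seen, and so was the choice of which classes to give hormone genes for besides their producers. The cell filter, the doublet share, the 2000 variable genes, the marker lists, the minimum of 100 cells, CPM + 5 and the alternatives below were also fixed then, except where stated. Other choices were made after seeing the data: the resolution and its 2 alternatives were chosen after clusterings at several resolutions had been looked at, and 0.5 was first meant as the main setting; the naming rule was written after clusters and their leading genes had been seen, and was revised once, when an earlier form had given a Gh-rich cluster an erythroid name with genes centred within each library; and the numbers of components and neighbours, the minimum of 5 CPM for a measured gene and the depths for thinning were not fixed in advance. Cells with a UMI of Mki67 or Top2a were counted after each cell was thinned to 2000 UMIs by a seeded draw, leaving out cells with fewer.

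Alternatives changed 1 choice at a time: a lenient (200 genes, 25% mt) and a strict (1000 genes, 10% mt) cell filter; no doublets removed; hormone genes included in clustering; genes centred and scaled within each library; resolution 0.5 or 1.5; cell cycle genes (the list and the 200 genes most correlated with it) left out of clustering, which was added after the data were seen; CPM over the other genes without hormone, mt-, ribosomal protein and haemoglobin genes; scaling to the median ratio over expressed genes; the mean over cells of each cell's CPM; a pseudocount of 1 or 20 CPM; no minimum or 50 CPM; and no thinning or 1000 UMIs. Cells are compared across settings by class name. The gene and list steps were tested on simulated Poisson counts drawn from the real library means: over all cells, all 50 simulated genes at each of 2-fold up, 2-fold down, 1.25-fold up and 0.8-fold were recovered among 5797 genes, 5.07% of unchanged genes had an interval without 1, and 2% of 200 unchanged lists fell outside percentiles 2.5 to 97.5. The intervals assume the same Poisson model, so this checks the computation and not the variation between cells or mice. Thinning was tested apart, on made-up counts: with 1 rate at 2 depths, shares of 33.1% and 55.6% became 18.8% and 18.0% after thinning. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Reads were not analysed here, and no reference cell atlas was used.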

Results

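Single cells of the postnatal day 4 female mouse pituitary were profiled by droplet RNA sequencing in 2 libraries, each from 1 mouse. One mouse carried Hesx1Cre/+, a Cre recombinase expressed from the Hesx1 gene in the early pituitary primordium (the control library). The other carried Hesx1Cre/+ with R26 dnRAR/dnRAR, 2 copies of a Rosa26 allele coding for a shortened human RARA receptor which blocks retinoic acid signalling (the dnRAR library). The comparison asks what blocked retinoic acid signalling in this lineage does to pituitary cell types and hormone expression. The control library held 52751396 UMIs in 7288 barcodes and the dnRAR library 47475549 UMIs in 7290 barcodes, of which 6235 and 5949 were kept as cells, with medians of 6592 and 6124 UMIs per cell. With 1 library per genotype there was no replicate check and no test of genotype. Every pair of values is given in the order control library, dnRAR library. Every ratio is the dnRAR over the control value, and every interval is a 95% interval that covers counting error only.

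The transgene is human and truncated, and its reads may not be counted under a mouse gene, so the labels were checked on neighbouring signals. Mouse Rara, the endogenous receptor gene (ENSMUSG00000037992, chromosome 11, 98927818 to 98974942, mm10), was at 20.1 (18.9 to 21.5) and 19.4 CPM (18.1 to 20.8). Rarb, a direct retinoic acid target (ENSMUSG00000017491, chromosome 14, 16430839 to 16819156), was at 18.1 (16.9 to 19.3) and 16.4 CPM (15.2 to 17.7); neither is part of the transgene. Gt(ROSA)26Sor, the transcript of the targeted Rosa26 locus (ENSMUSG00000086429, chromosome 6, 113067428 to 113077333), was at 67.7 (65.3 to 70.1) and 0.624 CPM (0.407 to 0.914). In the dnRAR library it was at 1.18 CPM or less in each of the 11 classes with at least 100 cells in both libraries. A custom feature named YFP in the deposited tables was at 0.4698 (0.294 to 0.711) and 72.5 CPM (69.98 to 75.2). The labels do not describe this feature, so whether it is part of the R26 dnRAR allele is unknown.

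Melanotrope-like cells, named after the producers of melanocyte-stimulating hormone in the intermediate lobe, had the share ratio furthest from 1 among the classes whose interval left out 1, and somatotrope-like cells had the widest difference in percentage points. Melanotrope-like cells were 1.19% (0.933 to 1.49) and 3.41% (2.97 to 3.91) of kept cells, a share ratio of 2.88 (2.19 to 3.805), from 74 and 203 cells. Gonadotrope-like cells were 7.28% (6.65 to 7.95) and 10.3% (9.51 to 11.1), a ratio of 1.41 (1.247 to 1.596). Stem/progenitor-like cells, which carried Sox2, Sox9 and Prop1, were 14.96% (14.1 to 15.9) and 20.1% (19.1 to 21.2), a ratio of 1.35 (1.23 to 1.47). The shares of somatotrope-like cells (28.3% (27.1 to 29.4) and 21.95% (20.9 to 23.03)), thyrotrope-like cells (4.72% (4.202 to 5.27) and 3.51% (3.06 to 4.01)) and pituicyte-like cells, glia of the posterior lobe (4.68% (4.17 to 5.24) and 3.14% (2.71 to 3.62)), were lower in the dnRAR library. Their ratios were 0.777 (0.723 to 0.835), 0.745 (0.621 to 0.893) and 0.671 (0.556 to 0.809). Fibroblast/mesenchymal-like cells were 6.303% and 5.38%, a ratio of 0.853 (0.734 to 0.992). Corticotrope-like cells were 11.5% and 11.3%, and the interval of their ratio, 0.988 (0.888 to 1.099), included 1. So did those of the proliferating (7.55% and 7.396%), lactotrope-like (4.89% and 4.14%), endothelial-like (1.78% and 2.19%), macrophage-like (1.33% and 1.06%), erythroid-like (0.898% and 0.807%), mural-like (0.481% and 0.689%) and glia/Schwann-like (0.128% and 0.235%) classes and of cluster 11 (4.07% and 4.35%). Cluster 11 met no class rule and carried Smoc2, Htr3a, Mycl, Isl1 and Hes6. Among hormone-producing and stem cells alone the melanotrope-like ratio was 2.799 and the somatotrope-like ratio 0.756. The lactotrope-like ratio was 3.29 with a lower cluster resolution, so no direction is given for that class.

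**Figure D1:**
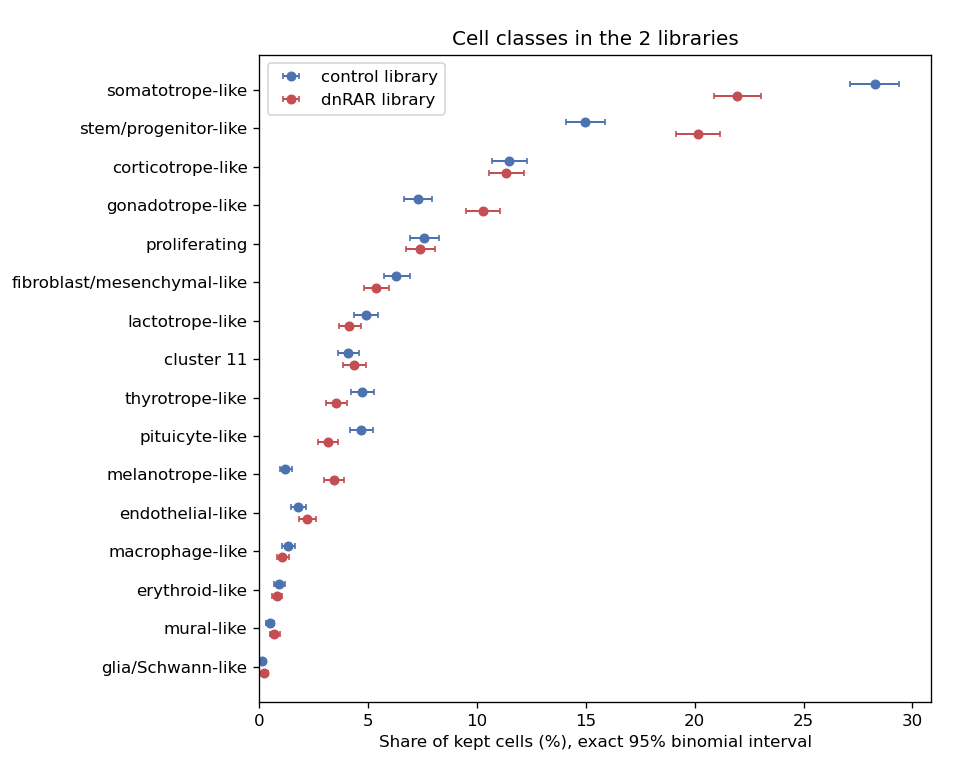
Share of kept cells in each class (%, horizontal axis) in the control (blue) and dnRAR (red) library; bars are exact 95% binomial intervals, counting error only. Melanotrope-like cells were 1.19% and 3.41%, and somatotrope-like cells 28.3% and 21.95%.

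Summed over all kept cells, Pomc, the precursor of adrenocorticotropic and melanocyte-stimulating hormone (ENSMUSG00000020660), and Lhb, the luteinizing hormone beta subunit (ENSMUSG00000100916), were near 2-fold higher in the dnRAR library, while Tshb, the thyroid-stimulating hormone beta subunit (ENSMUSG00000027857), was lower. Pomc was at 9582 and 19526 CPM, 2.04-fold (2.03 to 2.05), although the mean of each cell's own CPM gave 1.35. Lhb was at 1568 and 3079.6 CPM, 1.96-fold (1.95 to 1.98). Tshb was at 2431 and 1945 CPM, 0.8001-fold (0.793 to 0.807). Prl, prolactin (ENSMUSG00000021342), was at 255 and 343 CPM, 1.34-fold (1.31 to 1.37). Fshb, the follicle-stimulating hormone beta subunit (ENSMUSG00000027120), was at 86.7 and 125 CPM, 1.44-fold (1.39 to 1.505), with 0.968 from the mean of each cell's CPM. Gh, growth hormone (ENSMUSG00000020713), took 13.03% and 13.4% of kept UMIs, a ratio of 1.03 that was 0.966 under median-ratio scaling. Cga, the shared alpha subunit (ENSMUSG00000028298), had a ratio of 0.993, and 1.004 under the strict cell filter, so neither is given a direction.

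Within the producing classes, Pomc differed in opposite directions: it was at 71280.4 and 53909 CPM in corticotrope-like cells, 0.756-fold (0.752 to 0.761), and at 138156 and 240206 CPM in melanotrope-like cells, 1.74-fold (1.73 to 1.75). Lhb in gonadotrope-like cells was at 20258 and 28688 CPM, 1.42-fold (1.403 to 1.43), and Gh in somatotrope-like cells at 329930 and 403400 CPM, 1.22-fold (1.22 to 1.22). Prl in lactotrope-like cells was at 5354 and 9849 CPM, 1.84-fold (1.79 to 1.89), but 0.723 with a lower cluster resolution. Prl was at 111 and 22.9 CPM in somatotrope-like cells, 0.206-fold (0.179 to 0.237), and 62.05 and 15.6 CPM in gonadotrope-like cells, and Gh in lactotrope-like cells was at 95187 and 21853 CPM. Gh is also a leading gene of the lactotrope-like cluster. Which cells form that class depended on the cluster resolution, so its Gh values carry the same limit as its Prl values. Cga was 0.846-fold (0.841 to 0.851) in thyrotrope-like cells. In gonadotrope-like cells it was 1.19-fold (1.18 to 1.195), and 0.992 from the mean of each cell's CPM. Tshb in thyrotrope-like cells, at 42563 and 43852 CPM, had a ratio of 1.03 that lay below 1 under each of the 3 other scalings. Fshb in gonadotrope-like cells had a ratio of 1.02-fold (0.972 to 1.06). From the mean of each cell's CPM the Fshb ratio lay below this interval, as listed with the processing choices below. Of classes that should not make these hormones, endothelial-like cells held 818 and 1052 CPM of Pomc, 8653 and 11688 CPM of Gh, 195 and 139 CPM of Lhb, 12.3 and 13.8 CPM of Prl, 167 and 89.8 CPM of Tshb and 719 and 361 CPM of Cga. Other such classes differed from them: Pomc was 1.98-fold in somatotrope-like, 2.105-fold in stem/progenitor-like, 2.42-fold in thyrotrope-like and 0.959-fold in cluster 11 cells, and Lhb 2.92-fold in corticotrope-like, 1.898-fold in stem/progenitor-like and 0.662-fold in cluster 11 cells. No 1 class therefore gives the level of free RNA for the rest. The hormone list as a whole had a median log2 ratio of 0.42 (0.38 to 0.45) over all cells, and -0.04 from the mean of each cell's CPM.

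**Figure D2:**
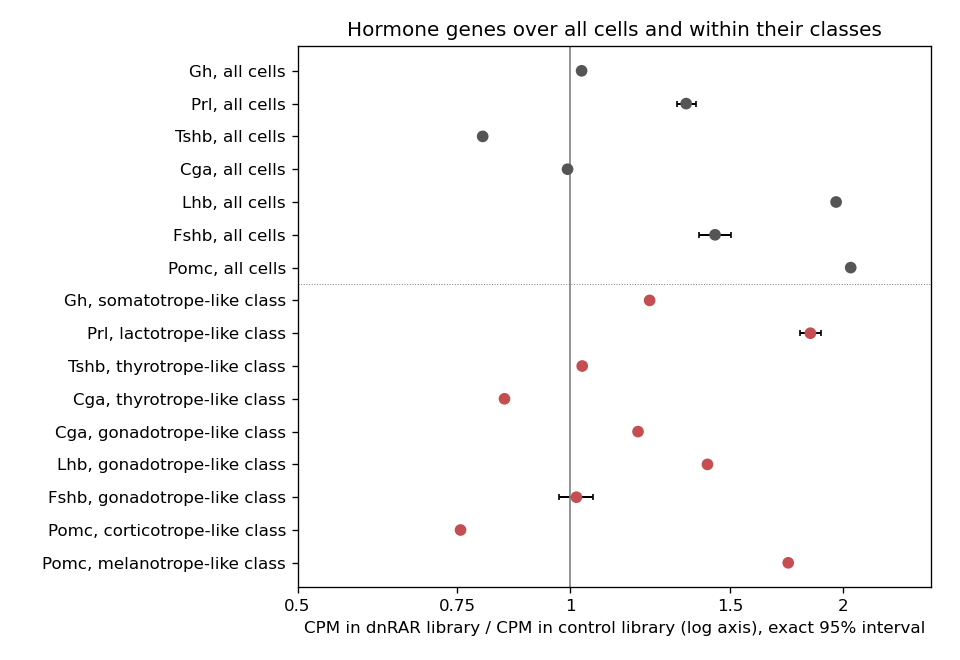
CPM in the dnRAR library divided by CPM in the control library (log axis) for hormone genes over all kept cells (grey) and within the class that makes each (red), with exact 95% intervals that cover counting error only. Pomc was at 0.756 in corticotrope-like and 1.74 in melanotrope-like cells.

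Retinoic acid target genes were higher in the dnRAR library in fibroblast/mesenchymal-like cells, while Rarb was lower in 4 hormone-producing classes. Reads of the transgene were not identified, so which of these classes made the shortened receptor is not known. In fibroblast/mesenchymal-like cells 7 of 9 measured targets were higher, with a ratio interval above 1, and the other 2 had ratios above 1 with intervals that included 1. The list had a median log2 ratio of 0.59 (0.47 to 0.76), at percentile 99.97 of 10000 matched random lists, with Crabp2 alone lower when no doublets were removed. The median of all expressed genes there was at 0.15. Cyp26a1, which degrades retinoic acid, was at 13.004 and 130.5 CPM there, 10.03-fold (6.64 to 15.7). Stra6, a retinol transporter, was at 34.01 and 77.3 CPM, Rarres2 at 132 and 264 CPM, Dhrs3, a retinaldehyde reductase, at 391 and 589.8 CPM and Rarb at 156 and 219.9 CPM. In endothelial-like cells Cyp26b1 was at 154 and 395 CPM, 2.56-fold (2.105 to 3.12), and Rarb at 46.03 and 102 CPM, but the target list there, at 0.43 (0.22 to 0.62) with 3 of 6 higher, was at percentile 83.85 and did not stand out from random lists. Rarb was lower in the dnRAR library in somatotrope-like (6.91 and 1.69 CPM), corticotrope-like (11.8 and 0.8997 CPM), lactotrope-like (6.84 and 0.7599 CPM), thyrotrope-like (6.33 and 0.586 CPM) and proliferating cells (11.2 and 1.31 CPM), each with a ratio interval below 1. The control values in somatotrope-like, lactotrope-like and thyrotrope-like cells were near the minimum of 5 CPM. In stem/progenitor-like cells the Rarb interval included 1, and in gonadotrope-like cells Rarb did not count as measured. Nrip1, a nuclear receptor corepressor, was at 46.4 and 15.1 CPM in somatotrope-like cells, 0.324-fold (0.2701 to 0.388), and at 157 and 105 CPM in stem/progenitor-like cells. The target list had median log2 ratios of -0.50 (-0.66 to -0.34) in somatotrope-like, -0.58 (-0.94 to -0.22) in lactotrope-like, -0.48 (-0.82 to -0.17) in thyrotrope-like and -0.66 (-0.89 to -0.45) in proliferating cells, at percentiles 0.94, 0.73, 2.28 and 0.13. In each of the 4 classes only 2 of 4 measured members were lower by their interval, and in lactotrope-like cells 1 was higher. In cluster 11 the median was 0.42 (0.03 to 0.82) at percentile 97.7, with 2 of 4 higher and 1 lower. The list was at -0.08 (-0.34 to 0.11) in corticotrope-like (percentile 15.97), -0.25 (-0.59 to 0.14) in gonadotrope-like (7.505), 0.13 (-0.12 to 0.39) in pituicyte-like (39.68) and -0.08 (-0.20 to 0.04) in stem/progenitor-like cells (11.04), and 0.13 (0.07 to 0.19) over all cells (5 of 10 higher and 1 lower, percentile 73.86). In stem/progenitor-like cells Crabp2, a retinoic acid carrier, was at 130.3 and 198 CPM and Dhrs3 at 10.3 and 3.78 CPM. The synthesis enzymes Aldh1a1 and Aldh1a2 were at 18.7 and 46.6 CPM, 2.49-fold (2.07 to 3.02), and 218 and 352 CPM; Aldh1a2 is a leading gene of clusters 4 and 19, which hold mostly dnRAR cells. Rbp4, the plasma retinol carrier, was at 105 and 328 CPM in gonadotrope-like cells, and Rdh11 at 24.6 and 14.03 CPM over all cells. Over all cells the remaining genes of both lists were at 5.62 and 5.85 CPM for Tgm2, 124 and 139 for Rbp1, 14.9 and 16.98 for Rdh10, 5.66 and 5.398 for Rarg, 7.28 and 5.81 for Rxra, 13.9 and 11.8 for Rxrb and 43.7 and 43.4 for Rxrg. Aldh1a3, Crabp1, Hoxa1 and Lrat stayed below 5 CPM over all cells, and Cyp26c1 had no UMI. Aldh1a3 did count as measured in fibroblast/mesenchymal-like cells, and Crabp1 there and in gonadotrope-like cells. The all-cell median of the synthesis and receptor list was -0.02 (-0.08 to 0.04).

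**Figure D3:**
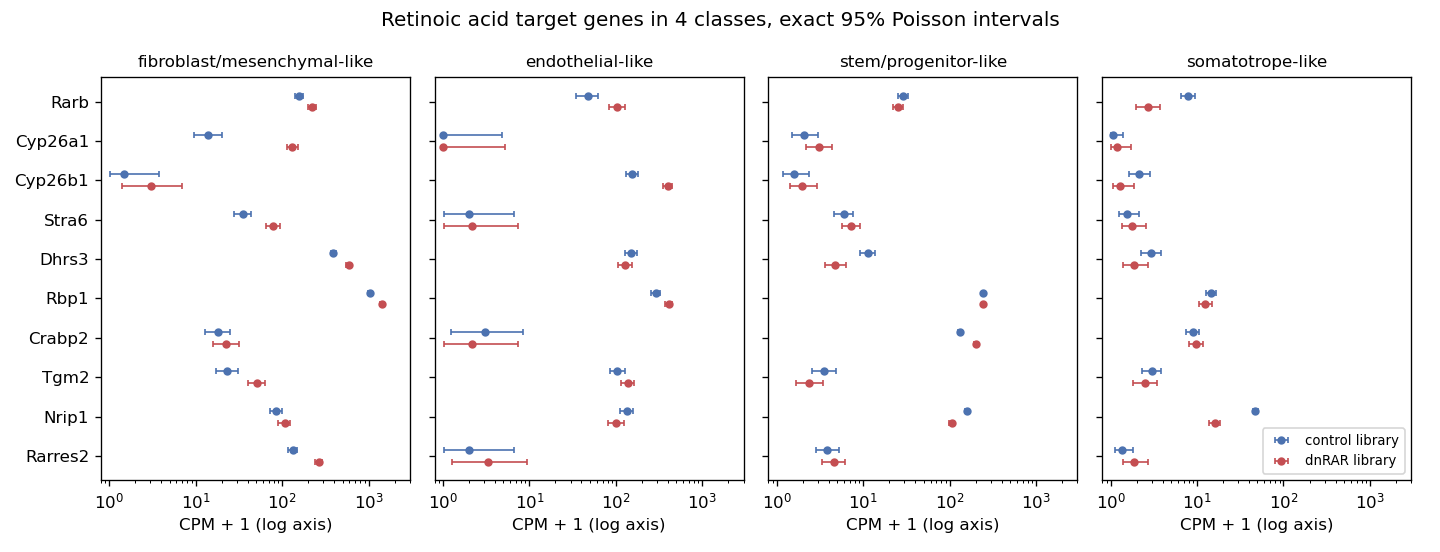
CPM + 1 (log axis) of 10 retinoic acid target genes in the control (blue) and dnRAR (red) library in 4 classes, with exact 95% Poisson intervals, counting error only. In fibroblast/mesenchymal-like cells Cyp26a1 was at 13.004 and 130.5 CPM; in somatotrope-like cells Nrip1 was at 46.4 and 15.1 CPM.

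Over all cells the genes furthest apart included melanotrope genes among those higher and stress genes among those lower in the dnRAR library. Higher were YFP, AC160336.1 (ENSMUSG00000115801; 62.5 and 422 CPM), Rab6b (1.79 and 22.4 CPM), the melanotrope gene Oacyl (11.7 and 55.8 CPM, 4.76-fold (4.34 to 5.24)) and Pcsk2, the prohormone convertase that cuts Pomc further in melanotropes (35.4 and 124 CPM, 3.49-fold (3.300 to 3.69)). Also higher were Akr1e1 (5.83 and 28.7 CPM), A330069E16Rik (18.96 and 62.97 CPM), the vasoconstrictor peptide gene Edn2 (32.4 and 99.9 CPM; a leading gene of cluster 4), C730034F03Rik (10.997 and 35.8 CPM) and the microfibril gene Mfap2 (140.2 and 312 CPM). Lower were Gt(ROSA)26Sor, the chaperone genes Dnajb1 (702 and 191 CPM, 0.272-fold (0.266 to 0.279)) and Dnaja4 (72.5 and 22.9 CPM) and Nfkbia, an inhibitor of NF-kappa-B (399 and 131 CPM). Also lower was the death receptor gene Fas (119 and 38.7 CPM), a leading gene of cluster 2. The others lower were the chemokine gene Cxcl1 (29.04 and 6.91 CPM), B430010I23Rik (20.3 and 3.45 CPM), and S100a9, S100a8 and BC100530. The last 3 were at log2 ratios of -2.18, -2.06 and -1.70, and at 0.65, 0.71 and 0.36 under the strict cell filter; S100a8 and S100a9 are neutrophil genes. Rab6b shares sequence with its paralog Rab6a, which was at 172 and 137 CPM, so the split of reads between these genes is uncertain.

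Of the 17 fixed gene lists, cell cycle and secretory granule genes were higher over all cells in the dnRAR library, and unfolded protein response and dissociation stress genes were lower. In the counts of list members that follow, higher or lower means a ratio interval without 1. All 22 cell cycle genes were higher, with a median log2 ratio of 0.50 (0.45 to 0.53), as were 16 of 18 secretory granule genes, with 1 lower, with a median of 0.29 (0.27 to 0.31), at percentiles 100 and 99.97 of matched random lists. Of the unfolded protein response genes 10 of 12 were lower and 2 higher, with a median of -0.61 (-0.62 to -0.59), and 11 of 12 immediate early and heat shock genes that mark dissociation stress were lower, with a median of -0.60 (-0.62 to -0.58), both at percentile 0. By ratio alone, 12 stress genes lay below 1, but only 8 from the mean of each cell's CPM, which put 21 cell cycle and 15 secretory granule genes above 1. The cells had been dissociated at 37°C, per the labels' protocols. The stress list lay below 0 in 8 of the 11 classes: its median was -1.28 in somatotrope-like, -1.25 in thyrotrope-like, -1.16 in fibroblast/mesenchymal-like, -1.03 in pituicyte-like, -0.95 in corticotrope-like, -0.91 in endothelial-like, -0.88 in proliferating and -0.66 in lactotrope-like cells. It was 0.15 in stem/progenitor-like cells, 0.01 in gonadotrope-like cells and 0.49 in cluster 11. The other lists had medians over all cells of 0.16 for pituitary transcription factors, 0.19 for Notch, 0.10 for hypothalamic and feedback receptors and 0.07 for thyroid hormone responsive genes. They were 0.05 for Wnt, -0.07 for BMP and FGF, -0.11 for p53 and apoptosis, -0.12 for interferon response and 0.07 for mitochondrial transcripts, a sign of RNA quality. Within classes the mitochondrial list was at 0.29 (0.25 to 0.33) in lactotrope-like (7 of 8 higher), 0.21 (0.19 to 0.23) in gonadotrope-like (7), 0.15 (0.13 to 0.18) in thyrotrope-like (6) and -0.20 (-0.23 to -0.16) in proliferating cells (7 lower), so RNA quality is open as a source of part of the differences there. Epithelial-mesenchymal transition genes were at -0.26, and at 0.09 among genes with at least 50 CPM. The median of all expressed genes was at 0.08 over all cells, 0.15 in stem/progenitor-like, 0.21 in lactotrope-like, 0.11 in pituicyte-like and 0.22 in endothelial-like cells. List medians in these classes are to be read against it.

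**Figure D4:**
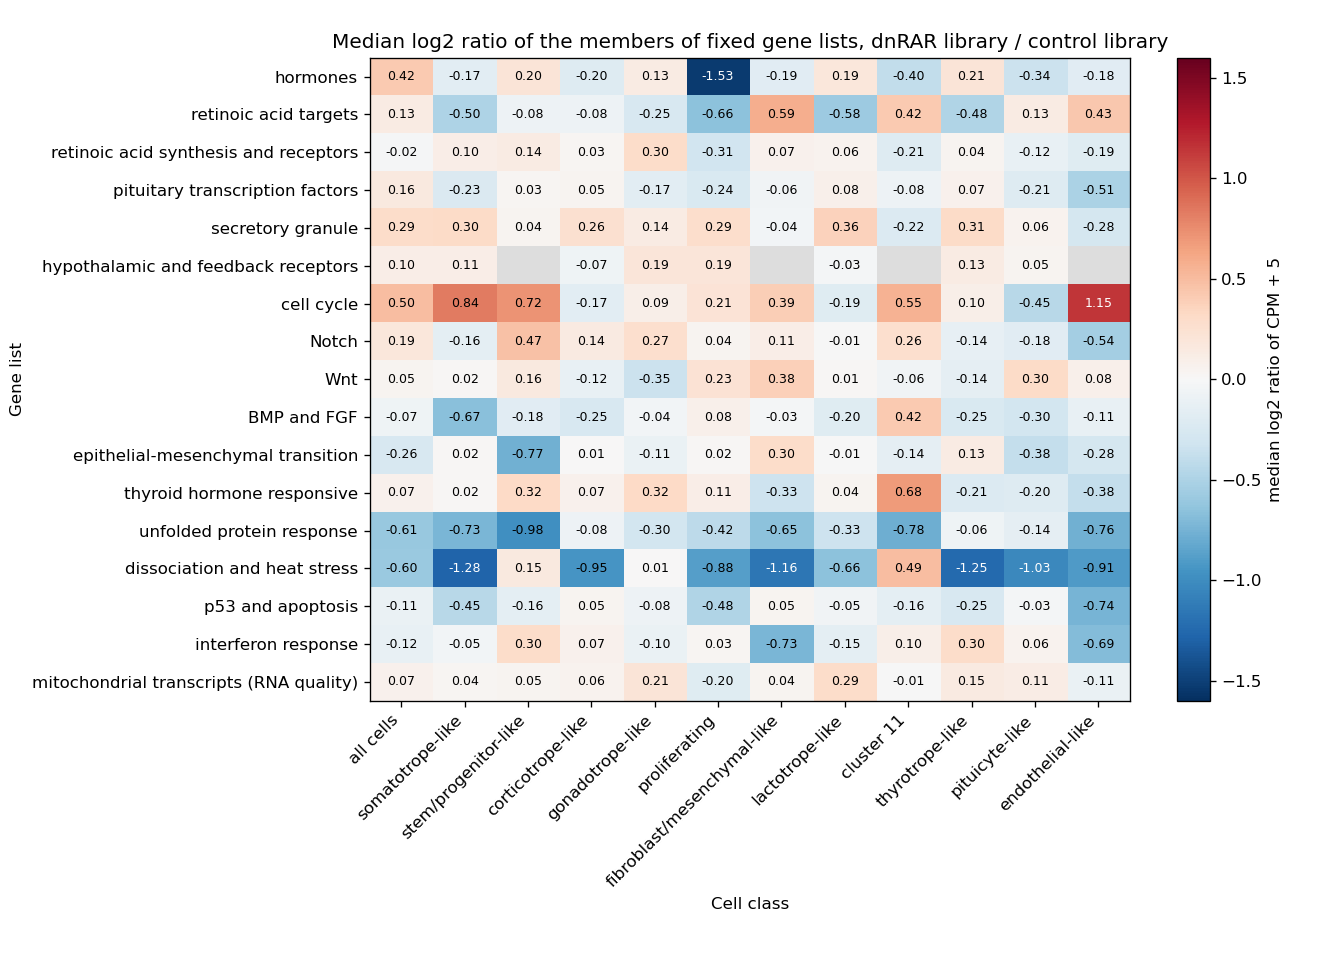
Median log2 ratio (dnRAR over control library, CPM + 5) of the measured members of 17 gene lists (rows) over all cells and in 11 classes (columns); grey squares had fewer than 3 measured members. Dissociation and heat stress genes were at -1.28 in somatotrope-like and 0.15 in stem/progenitor-like cells; cell cycle genes were at 1.15 in endothelial-like cells.

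Somatotrope-like cells of the dnRAR library had more cell cycle and secretory granule RNA and less stress and BMP and FGF pathway RNA, with the stress list at -1.28. Of 18 cell cycle genes 16 were higher, with a median of 0.84 (0.76 to 0.93), among them Top2a (5.56 and 20.1 CPM), Rrm2 (2.85 and 12.4 CPM), Tyms (23.8 and 62.9 CPM) and Mcm6 (17.03 and 41.2 CPM). Of 18 secretory granule genes 15 were higher and 1 lower, with a median of 0.30 (0.25 to 0.36), including the calcium sensor gene Syt1 (58.1 and 116 CPM) and Rab3b (98.4 and 179.5 CPM). Of 6 measured BMP and FGF genes 4 were lower and the others included 1, with a median of -0.67 (-0.84 to -0.50), including the BMP targets Id3 (45.5 and 15.2 CPM) and Id1 (10.9 and 2.78 CPM) and the ligand gene Bmp2 (7.41 and 2.48 CPM). Pituitary transcription factors had a median of -0.23 (-0.32 to -0.13), with Nr4a1 at 139 and 47.2 CPM, Lhx3 at 12.5 and 3.57 CPM, Neurod4 at 27.6 and 14.3 CPM and Nr5a1 at 2.42 and 7.73 CPM. Ghrhr, the growth hormone-releasing hormone receptor, was at 173 and 213 CPM. Among the furthest apart were YFP, 4930481A15Rik, AC160336.1, Akr1e1 and Mfap2 (32.8 and 95.4 CPM) on the higher side. On the lower side were Hspb1 (608 and 50.4 CPM), Gt(ROSA)26Sor, Dnajb1 (653 and 72.4 CPM), Hspa1a (2385 and 342 CPM), Hspa1b (539 and 76.4 CPM) and Serpinh1 (221 and 35.99 CPM), all but Gt(ROSA)26Sor chaperone genes. The p53 and apoptosis list was at -0.45, with Cdkn1a at 72.1 and 21.2 CPM, and the unfolded protein response list at -0.73, with Ddit3 at 265 and 63.05 CPM and Atf4 at 284 and 99.5 CPM. Klf9, of the thyroid hormone responsive list, was at 102 and 43.2 CPM, and Irf7, of the interferon response list, at 7.12 and 2.38 CPM. The lists as a whole did not shift with them. Their medians were 0.02 (-0.14 to 0.18; 1 of 4 higher and 1 lower) and -0.05 (-0.19 to 0.08; 0 of 4 higher and 1 lower). Different clusters held most of this class in each library: clusters 1 and 7 had 1114 and 541 control and 90 and 142 dnRAR cells, and clusters 3 and 20 had 94 and 13 control and 884 and 190 dnRAR cells. Cluster 20 has the replication genes Pclaf and Tcf19 among its 10 leading genes. Whether the class's cell cycle difference comes from this cluster was not tested.

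In stem/progenitor-like cells of the dnRAR library, cell cycle and Notch genes were higher and unfolded protein response and epithelial-mesenchymal transition genes lower. The stress list was at 0.15 here, with Fos at 791 and 1266 CPM and Dnajb1 at 1018 and 382 CPM. Of 22 cell cycle genes 21 were higher, with a median of 0.72 (0.65 to 0.79), among them Cenpf (51.8 and 141 CPM) and Top2a (68.8 and 147 CPM). Of 11 Notch genes 8 were higher (10 had a ratio above 1, and 9 from the mean of each cell's CPM), with a median of 0.47 (0.36 to 0.57) at percentile 99.01, including Hes6 (60.7 and 123 CPM), Hes5 (5.79 and 11.8 CPM) and Nrarp (33.5 and 53.3 CPM). Pituitary transcription factors went both ways, with 7 of 16 higher, 6 lower and a median of 0.03 (-0.08 to 0.14) at percentile 25.28. Furthest from 0 were Zeb2 (52.97 and 22.8 CPM, 0.431-fold (0.361 to 0.512)), Lhx3 (68.1 and 132 CPM, 1.94-fold (1.75 to 2.15)), Pitx1 (102 and 190.2 CPM, 1.86-fold (1.71 to 2.03)) and Six6 (157 and 285 CPM, 1.81-fold (1.695 to 1.94)). Prop1, named in the series title, was at 19.3 and 34.6 CPM, 1.797-fold (1.48 to 2.19). Wnt genes also split, with 5 of 10 higher, 3 lower and a median of 0.16 (0.01 to 0.31): the antagonist genes Sfrp1 (6.38 and 26.95 CPM), Sfrp5 (12.9 and 32.7 CPM) and Wif1 (2.72 and 8.05 CPM) were higher, and Nkd1, also an antagonist (49.5 and 34.6 CPM, 0.699-fold (0.599 to 0.815)), was lower. Of 13 BMP and FGF genes 6 were lower and 4 higher, with a median of -0.18 (-0.27 to -0.03) at percentile 1.64 that was 0.08 from the mean of each cell's CPM. Fgfr2 (51.8 and 32.2 CPM) was lower, and Id2 (105 and 287 CPM), Dusp6 (48.1 and 81.3 CPM) and Etv4 (6.27 and 9.76 CPM) were higher. Of 9 epithelial-mesenchymal transition genes 7 were lower and 2 higher, with a median of -0.77 (-0.88 to -0.63). The lower ones included the epithelial genes Cldn4 (594 and 282 CPM; a leading gene of cluster 2) and Cdh1 (90.1 and 49.998 CPM) as well as Zeb2 and Fn1 (46.8 and 25.4 CPM). The list holds both epithelial and mesenchymal genes, so its median gives no direction of a transition. Of 12 unfolded protein response genes 11 were lower, with a median of -0.98 (-1.04 to -0.92), including Ddit3 (216 and 61.6 CPM), Xbp1 (312 and 111 CPM) and Herpud1 (441 and 166 CPM). Of the thyroid hormone responsive list, Klf9 was at 206 and 95.4 CPM and Thrb, a thyroid hormone receptor, at 4.97 and 12.9 CPM. That list had a median of 0.32 (0.13 to 0.52) at percentile 74.7, with 2 of 4 higher and 1 lower. Of the interferon response list, Stat1 was at 9.22 and 17.3 CPM. Among the furthest apart were YFP, AC160336.1, A330069E16Rik (18.1 and 163 CPM), Rab6b, Pdgfrl (11.8 and 86.9 CPM) and C730034F03Rik (10.8 and 77.3 CPM) on the higher side. On the lower side were Gt(ROSA)26Sor, Creb5 (229 and 63.3 CPM), Ddit3, Akap12 (54.3 and 12.9 CPM) and Eppk1 (87.5 and 23.05 CPM). Cluster 2 held 797 control and 285 dnRAR cells of this class, and clusters 4 and 19 held 76 and 60 control and 760 and 153 dnRAR cells.

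In thyrotrope-like cells Nr5a1, a transcription factor gene of gonadotropes, was at 7.18 and 34.6 CPM, 4.82-fold (2.77 to 8.82), and Tgfbr3l at 61.6 and 277 CPM, 4.49-fold (3.72 to 5.44). Of the other gonadotrope markers, Lhb was at 219.9 and 863 CPM, Fshb at 4.64 and 50.4 CPM, Foxp2 at 8.87 and 23.5 CPM and Gnrhr at 1.69 and 8.21 CPM. The 6 markers are none of the fixed gene lists and were not compared with random lists. Lhb was also higher in corticotrope-like (110.0 and 321 CPM, 2.92-fold) and stem/progenitor-like cells (100.1 and 190.1 CPM, 1.898-fold), so free Lhb RNA is open as a source of part of its difference here. Also higher were Mgp (12.7 and 159 CPM), Phkb (9.29 and 42.2 CPM) and Vat1l (5.49 and 29.3 CPM). Lower in this class, whose stress list was at -1.25, were Hspb1, Dnajb1, Rasd1 (390.1 and 59.2 CPM), Hspa1a and Hspa1b. In gonadotrope-like cells, where the stress list was at 0.01, Slurp2 (17.1 and 82.1 CPM) was higher, and Th, tyrosine hydroxylase (25.9 and 1.42 CPM), and Vgf (30.4 and 4.97 CPM) were lower. Spp1, osteopontin, a leading gene of gonadotrope-like cluster 13, was at 303 and 35.03 CPM. Gm3488, higher, and Gm3526 and Gm3373, lower, belong to a family of near-identical genes, so the split of reads between them is uncertain. In corticotrope-like cells, with the stress list at -0.95, Egr3 (9.21 and 34.8 CPM) and Olfr655 (0.512 and 23.7 CPM) were higher. Lower were Hspb1 (1691 and 300.5 CPM), Calb1, calbindin (73.2 and 12.3 CPM), Id3 (46.6 and 10.2 CPM) and Fetub (47.9 and 11.1 CPM). Tbx19, the transcription factor gene of the Pomc lineage, was at 146 and 97.8 CPM. In lactotrope-like cells, with the stress list at -0.66, Loxl2 (0 and 44.1 CPM), Dio2, a thyroid hormone-activating deiodinase (6.84 and 39.5 CPM), and Mfap2 (83.3 and 318 CPM) were higher. Lower were Dnajb1 (1442 and 154 CPM), Klf2 (73.6 and 6.08 CPM) and Nfkbia (291 and 60.03 CPM). Which cells form the lactotrope-like class depended on the cluster resolution. In melanotrope-like cells, Pcsk2 was at 1292 and 1794 CPM, Oacyl at 613 and 952 CPM and Pax7, the transcription factor gene of melanotropes, at 67.98 and 80.8 CPM, the last with a ratio interval of 0.849 to 1.69.

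A larger share of cells in the dnRAR library had a UMI of the cell cycle genes Mki67 or Top2a, while the share in the proliferating clusters was near equal. No level of free RNA was taken off, so a cell with such a UMI need not be cycling. After every cell was thinned to 2000 UMIs, 8.13% (7.45 to 8.86; 485 of 5963 cells) and 11.1% (10.3 to 11.9; 628 of 5665 cells) had a UMI of Mki67 or Top2a, with 272 and 284 cells below that depth left out. Without thinning the shares were 14.9% and 17.9%. In somatotrope-like cells the thinned shares were 1.41% (0.903 to 2.08; 24 of 1707 cells) and 3.93% (2.93 to 5.15; 50 of 1273 cells), and 5.73% and 10.4% without thinning. In stem/progenitor-like cells they were 11.3% (9.305 to 13.5; 102 of 903 cells) and 15.2% (13.1 to 17.5; 163 of 1073 cells), and 24.4% and 24.9% without thinning. Thinned to 1000 UMIs they were 4.42% and 9.602%, a ratio of 2.17 against 1.34 at 2000 and 1.02 unthinned, so the size of this difference is uncertain. The seeded draws were not repeated, so how far the ratio varies between draws is not known. The cut at 2000 UMIs left out 30 control and 125 dnRAR cells of this class. Its cells had median depths of 5937 and 4892 UMIs. Of the other classes, gonadotrope-like cells had thinned shares of 0.973% and 1.201% at median depths of 6468 and 6485 UMIs, and pituicyte-like cells 1.71% and 1.61% at 9550.5 and 8366 UMIs. The shares were 1.85% and 3.73% in corticotrope-like, 0.337% and 1.24% in lactotrope-like and 4.94% and 7.72% in fibroblast/mesenchymal-like cells, ratios of 2.02, 3.68 and 1.56 from overlapping intervals, so ratios of this size also occurred where few cells had such a UMI. Cluster 11 (2.79% and 1.98%) and thyrotrope-like cells (2.13% and 1.47%) went the other way, also from overlapping intervals. The proliferating clusters themselves held 7.55% and 7.396% of kept cells. Within them Pcsk2 was at 26.7 and 175 CPM and Oacyl at 5.47 and 43.6 CPM. Lhb was at 1534 and 251 CPM, Cga at 5266 and 1161 CPM, Fshb at 74.3 and 5.45 CPM, and Tshb at 1270 and 438 CPM. The other hormone genes were higher: Gh at 240099 and 281361 CPM, Pomc at 10868.5 and 23262 CPM, and Prl at 111 and 137 CPM. Gh is a leading gene of both proliferating clusters, whose cells are not counted in the somatotrope-like share. Also higher there were AC160336.1, Sult5a1 (2.73 and 30.9 CPM) and Pttg1 (14.4 and 164 CPM), and lower Prss28 (37.4 and 0.872 CPM), Hspb1, Nfkbia, Dnajb1 and Jun, with the stress list at -0.88.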

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

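Every test of an explanation below was chosen after the result it concerns was seen. The YFP feature, a custom entry that is no mouse gene and that the labels do not describe, stood above its level in the control library: it was at 72.5 CPM over all cells of the dnRAR library and 0.4698 CPM in the control library. The other results here stand out because 2 cell classes of the same libraries lay on opposite sides or far apart, and the difference between classes was not tested. The Pomc ratio was 0.756 in the corticotrope class and 1.74 in the melanotrope class, and the Cga ratio was 0.846 in the thyrotrope and 1.19 in the gonadotrope class. From the mean of each cell's CPM both Cga ratios lay below 1. The median log2 ratio of the cell cycle list was -0.17 in the corticotrope and 0.72 in the stem/progenitor class. In the corticotrope class the intervals of 10 of 17 members included 1, and the thinned share of cells with a UMI of Mki67 or Top2a was 1.85% and 3.73%, the other way. The median of the stress list was 0.15 in the stem/progenitor, -1.28 in the somatotrope and -0.95 in the corticotrope class.

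Dissociation and heat stress genes were lower in the dnRAR library. CPM already scales by total depth, so depth was not tested apart from it. A difference in the share of counts taken by hormone, mt-, ribosomal protein and haemoglobin genes is argued against. Without those genes the list median over all cells was -0.64 (-0.66 to -0.62), against -0.60 with them. The mean of each cell's CPM gave a smaller difference, as listed with the processing choices below. A handling difference that moved the whole list alike in every class is argued against by a median of 0.49 (0.37 to 0.62) in cluster 11. That was the highest of the 11 class medians, and 8 of 11 lay below -0.3. Members did not move together: in stem/progenitor-like cells 7 were higher and 5 lower, with Fos at 1.6-fold and Dnajb1 at 0.375-fold. Dnajb1 and Atf3 were at least 2-fold lower in 9 of the 11 classes, and Jun in 8. A handling difference on such members alone therefore stays open. A handling difference that acted unequally on the classes cannot be told apart from genotype with 1 library per genotype, and an effect of the genotype stays open, untested.

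Melanotrope-like cells made up a larger share of the dnRAR library. More of the attached intermediate and posterior lobes together is argued against by a pituicyte share ratio of 0.671 (0.556 to 0.809), although more intermediate lobe alone stays open. Corticotrope-like cells counted as melanotrope-like are argued against by the all-cell CPM of Pax7, Pcsk2 and Oacyl, whose lowest ratio was 3.14 (2.41 to 4.12), for Pax7, and which needs no classes. Variation between mice cannot be told apart from genotype with 1 mouse per genotype, and an effect of the genotype stays open, untested.

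Besides YFP, 6 genes were at least 2-fold higher in 8 or more of 11 classes of the dnRAR library: Gm35082, AC160336.1, Rab6b, 2610035D17Rik, Akr1e1 and 4930481A15Rik. DNA linked to the Rosa26 allele is argued against by position, since 0 of the 6 lie within 20 Mb of Gt(ROSA)26Sor. For Rab6b and Gm35082 the values needed by Rab6a reads counted for its paralog and its neighbour are there: the summed CPM of the 3 genes had a ratio of 0.9801 (0.949 to 1.01), with Rab6a alone at 0.794 (0.767 to 0.821). Unlinked strain variants cannot be told apart from genotype with 1 mouse per genotype, and an effect of the genotype stays open, untested. On the other side, Gt(ROSA)26Sor, Atf3, Trib3, Jun, Hspb1, Dusp8, Ddit3, Irs2, Dnajb1, Nfkbia and Maff were at least 2-fold lower in 8 or more of the 11 classes. Of these, Atf3, Jun and Dnajb1 are members of the stress list.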

How the results depend on the processing

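Each choice was changed alone, and class values are compared by class name. The share ratios ranged from 2.600 to 2.98 for melanotrope, 0.698 to 0.836 for somatotrope, 1.26 to 1.402 for stem/progenitor, 1.248 to 1.56 for gonadotrope, 0.693 to 0.753 for thyrotrope and 0.662 to 0.678 for pituicyte cells, each on 1 side of 1. The direction was the same for 5762 of 5863 alternative values of genes, 2618 of 2815 of lists, 129 of 141 of hormones, 136 of 148 of shares and all 6 of cells kept. Of the others, 2, 13, 7 and 0 were reversed with values on the other side beyond counting error, as marked below. For the mean of each cell's CPM, the interval used was that of the summed counts, moved to the new value. It does not cover the spread between cells, so reversals marked there are less certain. The cause of the reversals was not tested. Cluster resolution and the naming rule were chosen after seeing the data, so class results depend on them: the lactotrope share and Prl in that class turned with the lower resolution, which was first meant as the main setting. The thinned shares left out cells below 2000 UMIs, and classes under 100 cells in a library were too shallow for gene values beyond hormones and markers. No paired analysis was possible because each genotype had 1 library.

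With the lenient cell filter, cells kept were 6607 and 6533 (control and dnRAR). Ratios were lactotrope share 1.18, Gh 1.02, Tshb 0.819, Cga 0.983, Lhb 1.99, Pomc 2.05, Gh in somatotrope 1.23, Pomc in corticotrope 0.766, Cga in gonadotrope 1.196, Lhb in gonadotrope 1.46, Prl in lactotrope 1.41, Tshb in thyrotrope 1.09, Cga in thyrotrope 0.881 and Pomc in melanotrope 1.78. Log2 ratios were cell cycle in pituicyte 0.48 (reversed). With the strict cell filter, cells kept were 5801 and 5535 (control and dnRAR). Ratios were Gh 1.04, Prl 1.41, Tshb 0.824, Cga 1.004, Lhb 2.05, Fshb 1.56, Pomc 1.98, Gh in somatotrope 1.23, Pomc in corticotrope 0.732, Cga in gonadotrope 1.21, Lhb in gonadotrope 1.46, Prl in lactotrope 1.599, Tshb in thyrotrope 1.104 and Cga in thyrotrope 0.875. Log2 ratios were S100a8 0.71 (reversed) and S100a9 0.65 (reversed). With no doublets removed, cells kept were 6601 and 6298 (control and dnRAR). Ratios were Gh 1.02, Prl 1.38, Tshb 0.818, Lhb 1.99, Pomc 2.02, Pomc in corticotrope 0.751, Prl in lactotrope 1.75, Tshb in thyrotrope 1.12, Cga in thyrotrope 0.894 and Pomc in melanotrope 1.76. Log2 ratios were cell cycle 0.54, mitochondrial transcripts (RNA quality) in fibroblast/mesenchymal -0.31 (reversed) and hormones in pituicyte 0.998 (reversed). At the lower cluster resolution, ratios were lactotrope share 3.29, somatotrope share 0.698, Gh in somatotrope 1.28, Cga in gonadotrope 1.21, Lhb in gonadotrope 1.44 and Prl in lactotrope 0.723 (reversed). Log2 ratios were mitochondrial transcripts (RNA quality) in somatotrope -0.022 (reversed). With cell cycle genes left out of clustering, an alternative chosen after seeing the data, ratios were somatotrope share 0.836, Gh in somatotrope 1.19, Pomc in corticotrope 0.744, Cga in gonadotrope 1.16, Lhb in gonadotrope 1.37 and Cga in thyrotrope 0.852. Log2 ratios were mitochondrial transcripts (RNA quality) in somatotrope -0.013 (reversed). With CPM of the other genes only, ratios were Gh 1.001, Prl 1.305, Tshb 0.778, Cga 0.965, Lhb 1.91, Pomc 1.98, Gh in somatotrope 1.32, Pomc in corticotrope 0.725, Prl in lactotrope 1.62, Tshb in thyrotrope 0.987 (reversed), Cga in thyrotrope 0.8100 and Pomc in melanotrope 1.95. Log2 ratios were secretory granule 0.25, unfolded protein response -0.65, dissociation and heat stress -0.64 and mitochondrial transcripts (RNA quality) in stem/progenitor -0.039 (reversed). Under median-ratio scaling, ratios were Gh 0.966 (reversed), Prl 1.26, Tshb 0.752, Cga 0.933, Lhb 1.84, Fshb 1.36, Pomc 1.91, Gh in somatotrope 1.26, Pomc in corticotrope 0.712, Prl in lactotrope 1.57, Tshb in thyrotrope 0.951 (reversed), Cga in thyrotrope 0.781 and Pomc in melanotrope 1.87. Log2 ratios were retinoic acid targets 0.060, retinoic acid synthesis and receptors -0.085, secretory granule 0.20, cell cycle 0.42, unfolded protein response -0.70, dissociation and heat stress -0.69, mitochondrial transcripts (RNA quality) -0.025 (reversed), mitochondrial transcripts (RNA quality) in stem/progenitor -0.12 (reversed) and mitochondrial transcripts (RNA quality) in fibroblast/mesenchymal -0.12 (reversed). From the mean of each cell's CPM, ratios were Gh 0.9505 (reversed), Prl 1.09, Tshb 0.677, Cga 0.842, Lhb 1.65, Fshb 0.968, Pomc 1.35, Gh in somatotrope 1.22, Pomc in corticotrope 0.712, Cga in gonadotrope 0.992 (reversed), Lhb in gonadotrope 1.21, Fshb in gonadotrope 0.705, Tshb in thyrotrope 0.929 (reversed), Cga in thyrotrope 0.789 and Pomc in melanotrope 1.64. Log2 ratios were hormones -0.044 (reversed), retinoic acid targets 0.25, secretory granule 0.18, cell cycle 0.32, unfolded protein response -0.63 and dissociation and heat stress -0.41. With no minimum CPM, log2 ratios were retinoic acid targets 0.064. Among genes with at least 50 CPM, log2 ratios were secretory granule 0.36, epithelial-mesenchymal transition 0.090 (reversed) and BMP and FGF in pituicyte 0.23 (reversed). With a pseudocount of 20 CPM, log2 ratios were cell cycle 0.37 and unfolded protein response -0.57. With genes centred within each library, ratios were Gh in somatotrope 1.21, Pomc in corticotrope 0.741, Cga in gonadotrope 1.21, Lhb in gonadotrope 1.45, Prl in lactotrope 1.94, Tshb in thyrotrope 1.05, Cga in thyrotrope 0.863 and Pomc in melanotrope 1.84. Log2 ratios were hormones in somatotrope 0.075 (reversed). With hormone genes in the clustering, ratios were Pomc in corticotrope 0.762, Cga in gonadotrope 1.14, Lhb in gonadotrope 1.37, Prl in lactotrope 1.66, Tshb in thyrotrope 1.05 and Cga in thyrotrope 0.861. Without thinning, ratios were share of cells with an Mki67 or Top2a UMI 1.198.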

Other observations

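Outside the hormone-producing classes, cell cycle RNA differed by class. In endothelial-like cells 20 of 22 genes had a ratio interval above 1, with a median log2 ratio of 1.15 (0.98 to 1.32), including Rrm2 (22.5 and 102 CPM) and Ccnb1 (12.3 and 62.2 CPM). The share of these cells with a UMI of Mki67 or Top2a, thinned to 2000 UMIs, was near equal: 20% (12.8 to 28.9; 21 of 105 cells) and 20.6% (13.9 to 28.8; 26 of 126 cells). Also higher there were Hebp1 (11.3 and 102 CPM), Cda (8.18 and 69.1 CPM), the cadherin gene Cdh2 (12.3 and 77.1 CPM), Igfbp5 (32.7 and 158 CPM) and Gfod2 (13.3 and 66.8 CPM), and lower were Rbp7 (99.2 and 10.4 CPM), Gla (56.3 and 4.604 CPM) and the chemokine gene Cxcl1 (201 and 27.6 CPM), in a class whose stress list was at -0.91. In fibroblast/mesenchymal-like cells 8 of 22 cell cycle genes were higher and the others included 1, with a median of 0.39 (0.25 to 0.52). In pituicyte-like cells 9 were lower and 2 higher, with a median of -0.45 (-0.66 to -0.26) at percentile 0 that turned to 0.48 with the lenient cell filter, 0.09 with hormone genes in the clustering and 0.02 with no doublets removed, so no direction is given. In fibroblast/mesenchymal-like cells Pclaf was at 24.5 and 104 CPM and Bicd1 at 6.002 and 30.3 CPM, while Cck, cholecystokinin (48.5 and 1.35 CPM), Klf2 (1352 and 199 CPM) and Usp2 (73.02 and 7.398 CPM) were lower and the stress list was at -1.16. Interferon response genes had medians of -0.73 (-1.03 to -0.52) in fibroblast/mesenchymal-like (5 of 7 lower) and -0.69 (-0.88 to -0.47) in endothelial-like cells (5 of 8 lower). They were at 0.30 (0.16 to 0.44) in stem/progenitor-like (6 of 7 higher, percentile 74.495) and 0.30 (0.04 to 0.56) in thyrotrope-like cells (0 of 6 higher).

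In pituicyte-like cells, with the stress list at -1.03, the sulfotransferase gene Chst1 (29.4 and 118 CPM), Irs4 (13.8 and 55.5 CPM), Fbxo44 (25.2 and 86.97 CPM) and Ntm (45.99 and 142 CPM) were higher in the dnRAR library, and the activity-regulated gene Arc (201 and 27.8 CPM), Igfbp7 (87.8 and 11.7 CPM) and Gadd45g (126 and 20.97 CPM) were lower. In cluster 11, with the stress list at 0.49, the transcription factor gene Pou3f4 (11.7 and 106 CPM), Gfod2 (11.7 and 107 CPM) and Stab1 (1.38 and 40.3 CPM) were higher, and the metallothionein gene Mt1 (1126 and 318 CPM), Ddit3 (492 and 149 CPM) and Dlx5 (62.1 and 16.8 CPM) were lower.

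YFP, at 0.4698 and 72.5 CPM over all cells, was at 0 and 211 CPM in fibroblast/mesenchymal-like, 0 and 196 in pituicyte-like, 0 and 163 in endothelial-like, 0.355 and 103 in stem/progenitor-like and 0.285 and 36.7 in somatotrope-like cells. Erythroid-like cells of the dnRAR library held 1 UMI in 48 cells, 13.98 CPM (0.354 to 77.9).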
